A study of Mus musculus with 38 samples.

How the data were processed

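Gene expression was measured by RNA sequencing of libraries prepared from 2000 sorted cells each with 12 cycles of amplification, per the labels. Each library had 1 column in 1 of 4 deposited tables, and groups were taken from the labels of the samples. The deposited values were unnormalized expected counts (estimated counts) per gene symbol that the authors made with RSEM 1.3.3 on the mm10 genome, per the submitters' processing notes. They are whole numbers and were read as rounded estimates, while the aligner, the annotation release and the rounding were not given in the sources used here. Columns within a table had different totals, and no column was left out. Of 31053 symbols, 30464 (98.1%) were found in the GENCODE M21 annotation, which gave gene positions and lengths.

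Counts were tested with R 4.3.3 and edgeR 4.0.16. Genes with enough counts in the libraries of a fit were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), library sizes were scaled with TMM, and groups were compared by the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The CNS and dLN genotype comparisons were fitted within their own table. The in vitro contrasts and their interaction came from 1 fit of 16 libraries, and the tissue contrast and its interaction with genotype from 1 fit of the 14 CHD1 libraries. A positive genotype by tissue value is a more positive cKO effect in the CNS. For these last 2 results the CHD1 CNS and dLN tables were joined, so tissue is confounded with table there. The other tables were not joined.

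Levels were CPM, the counts of a gene scaled to all deposited counts of a library. Overlap of groups was judged on these values without TMM scaling, so unequal shares of repeat and ribosomal RNA counts can add to it. A count of 0 was given a limit of 3 counts, which is 0.479 to 0.611 CPM in the CHD1 CNS libraries, 0.582 to 0.953 in the dLN, 0.328 to 0.478 in the GR libraries and 0.634 to 0.903 in vitro. Where a whole group was listed at 0, the bound on a fold change was computed in CPM with 3 counts over the group, without TMM scaling. The labels name no molecular identifiers, so these limits cover counting error only.

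The 27 gene lists held 570 symbols, of which 3 were absent from the tables. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it, and p values were adjusted over the lists of a comparison. Counts adjusted over the list alone used the edgeR p values of its members. Some lists share members with others, so their calls are not independent. Correlations of fold changes were taken across genes tested in both comparisons, with exact permutation tests over the splits of the labels of 1 comparison. The pair with shared WT control libraries was set against 100 simulations without any effect.

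Genes were named by a rule. It took Chd1, Nr3c1 and Il23r in every library of their tables, and a fixed set that included Il17a, Il17f, Csf2, Ifng, Fkbp5 and Tsc22d3 in every comparison. It then took up to 10 genes per direction with the largest change among called genes whose groups did not overlap and whose higher group averaged at least 10 CPM, without predicted, mitochondrial and sex genes. Where fewer than 10 genes were called, it took the 10 with the smallest p at the same minimum. Up to 4 members of a list were eligible where the list was described. The text gives a selection of the genes eligible under the rule. Some genes the rule names, and results that need them, are not reported here. Trbv16, Trav9-3, Cd4, Lyz2 and the members of the HIF target list were taken outside the rule for checks of the cell mixture and of low oxygen, after values had been seen.

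The alternatives tried were DESeq2 1.42.0 in place of edgeR, its size factors in edgeR, no filter on low counts, a filter at a mean of 10 CPM, a replicate block where numbers are shared (fixed, or random in limma), a joint fit of both tissues, a fit of only the 8 libraries compared, camera with an estimated correlation, fry, Spearman correlation, and leaving out each replicate in turn. Chosen after seeing the data were the removal of repeat and ribosomal RNA features, that removal with every library thinned to equal depth, a covariate of macrophage and antigen-presentation genes, and fits without doubted libraries. The code was tested on simulated data with known changes. Within-group pairs of libraries were checked for duplicates on genes with at least 20 counts. None of 54 pairs was as close as repeat sequencing of 1 library would be, the lowest chi-square per degree of freedom being 3.74. This check cannot find separate libraries made from the same cells. Among the KO controls, libraries 6 and 8 (3.74) and libraries 5 and 7 (4.44) lay closer than the other pairs (12.9 to 20.1). Whether they shared a culture is not known. Figures and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.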

Results

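Messenger RNA was counted per gene in libraries made from 2000 sorted mouse Th17 cells each. The in vivo libraries came from transferred T cells carrying the 2D2 receptor, which recognises a myelin protein, recovered at the peak of experimental autoimmune encephalomyelitis (EAE). Cells from the central nervous system (CNS) were compared between CHD1 WT (n = 3) and CHD1 cKO (n = 4) donors and, in a separate table, between glucocorticoid receptor (GR) WT (n = 4) and GR cKO (n = 4) donors. Cells from the draining lymph node (dLN) were compared between CHD1 WT (n = 3) and CHD1 cKO (n = 4) donors. Throughout, n counts libraries, and the number of donors is not known. The in vitro table holds WT and IL-23R KO Th17 cultures kept for 2 days with or without dexamethasone (Dex), n = 4 in each of the 4 groups. Libraries held 4911109 to 6262849 counts in the CHD1 CNS table, 3148634 to 5158450 in the dLN table, 6281769 to 9159671 in the GR table and 3320586 to 4732419 in vitro. Levels are given as CPM (counts of a gene scaled to the total of all counts in its library), as mean ± SD, and log2 fold changes come from the scaled model fit with their standard error (SE). All adjusted p values of genes are from the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment. The labels do not say that replicates were separate animals or cultures, so these p values measure only the spread between these libraries.

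The targeted genes gave unequal checks of the labels. Nr3c1, which encodes GR (ENSMUSG00000024431.15; mm10 chromosome 18, 39410545 to 39519421), stood at 18.0, 14.9, 11.1 and 14.3 CPM in GR WT libraries 1 to 4. It stood at 5.66, 5.50, 5.68 and 5.25 CPM in GR cKO libraries 5, 6, 7 and 9. Every GR cKO value therefore lay under every WT value, while part of the transcript remained. Chd1 (ENSMUSG00000023852.14; chromosome 17, 15704967 to 15772610) did not check the CHD1 labels. In the CNS it stood at 5.11, 6.14 and 4.24 CPM in WT libraries and 6.52, 6.87, 3.56 and 5.27 CPM in cKO libraries. In the dLN it stood at 5.47, 5.40 and 4.27 CPM in WT and 4.57, 6.04, 2.28 and 2.71 CPM in cKO libraries. Il23r (ENSMUSG00000049093.9; chromosome 6, 67422932 to 67491855) was still counted in the libraries labelled KO. Without Dex it stood at 7.89, 8.66, 6.70 and 6.33 CPM in WT and 4.21, 6.22, 2.25 and 5.39 CPM in KO libraries. With Dex it stood at 12.7, 16.6, 5.57 and 8.59 CPM in WT and 1.12, 2.11, 1.60 and 1.73 CPM in KO libraries. The tables count whole genes, so transcript left outside a deleted part is counted too, and the CHD1 and IL-23R genotypes rest on the labels.

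Receptor genes were counted to follow the 2D2 cells. Trbv16, the V segment of the 2D2 beta chain, took 98.1, 91.8, 96.9 and 98.7% of Trbv counts in CHD1 cKO dLN libraries 1 to 4. It took 99.4 ± 0.152% in WT dLN libraries and at least 99.0% in every CNS library. The Trav9-3 segments, of the 2D2 alpha chain, took 85.9, 72.9, 82.2 and 87.3% of Trav counts in CHD1 cKO dLN libraries 1 to 4 and 88.9 to 90.4% in WT dLN libraries. In vitro, where the cells carried mixed receptors, Trbv16 took at most 10.7%. The sex genes gave 1 pattern within each table. Repeat and ribosomal RNA features took 42.4 to 60.1% of the counts in the dLN libraries, 13.3 to 33.2% in the CHD1 CNS libraries, 31.6 to 42.2% in the GR libraries and 14.3 to 38.4% in vitro. In vitro the KO libraries with Dex held 31.4 to 38.4% of such counts, more than any other group of that table. Their raw CPM values are therefore low for all other genes relative to the scaled fold changes. Csf2 was at most 1.28 CPM in any library. Of the genes fixed for report in every comparison (Il17a, Il17f, Csf2, Ifng, Fkbp5 and Tsc22d3), those not named for a comparison did not pass its threshold or had too few counts to be tested.

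The first in vitro question was which genes Dex changed in WT Th17 cells. Tsc22d3 (chromosome X, 140539528 to 140600659) was 72.4 ± 16 CPM with Dex and 26.5 ± 3.93 CPM without (n = 4 each), 2.98-fold higher (edgeR adjusted p = 1.06e-04). Fkbp5 was 2.08-fold higher (9.28 ± 1.21 against 4.82 ± 0.973 CPM, adjusted p = 0.00117), and Sgk1 was 3.15-fold higher (adjusted p = 2.90e-05). Il5 fell from 49.5 ± 13.3 to 1.52 ± 1.02 CPM (log2 fold change -4.86 ± 0.32, adjusted p = 1.72e-07) and Il2 from 120.0 ± 29.8 to 19.5 ± 5.66 CPM (log2 fold change -2.52 ± 0.37, adjusted p = 3.88e-04). Il17f (log2 fold change 1.36 ± 0.43, adjusted p = 0.0599) and Il17a (0.29 ± 0.59, adjusted p = 0.823) did not pass the threshold.

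In all, 874 of 10813 genes passed the threshold with Dex in WT cells, 420 higher and 454 lower. Of these, 106 rose and 94 fell by at least 1 on the log2 scale. The count was 571 without WT Dex library 3 and 531 without WT control library 2. In CPM, which is not scaled for repeat counts, the groups did not overlap for 1959 genes (18.1%), where chance gives 2.86%. The largest rises included Gpnmb (log2 fold change 3.20 ± 0.37), Plaur (3.09 ± 0.31), Neb (2.79 ± 0.14) and Tgfb3 (2.28 ± 0.25). The largest falls included Pth (-6.75 ± 0.50), Il13 (-3.33 ± 0.33), Il3 (-2.43 ± 0.29) and Il4 (-1.92 ± 0.22). Among 23 gene lists fixed before the data were examined, 12 were called by camera with a preset correlation. The NF-kB and cytokine list was lower, with 13 of 24 members past the threshold over all genes tested and 16 lower and 2 higher adjusted over the list alone (mean log2 fold change -1.08). It was the only WT Dex list that held with an estimated correlation (camera adjusted p = 1.46e-04 with an estimated correlation). Glucocorticoid-induced genes were higher, with 7 of 20 members past the threshold and 12 higher and 2 lower adjusted over the list alone. The Th17 identity list was also higher (4 of 17 members higher and 1 lower; 9 and 2 adjusted over the list alone), but not without WT Dex library 2 (camera adjusted p = 0.0540). The pathogenic Th17 list was lower (1 of 15 members higher and 4 lower; 2 and 7 adjusted over the list alone). Oxidative phosphorylation, co-inhibitory receptor, Th1, Tfh and immediate early genes were lower, and stem-like, ribosomal protein and cytokine receptor genes were higher. The Tfh call was lost without WT Dex library 1 or 2 or WT control library 1 or 4 (camera adjusted p from 0.0585 to 0.0713). It was also lost with a mean of at least 10 CPM, in a fit of only the 8 libraries compared, with repeat counts removed and equal depth, and with no filter on low counts, where its mean was 0.11 against -0.20. The cytokine receptor call was lost without WT Dex library 2 or WT control library 1 or 2 (0.0598 to 0.0840).

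**Figure D1:**
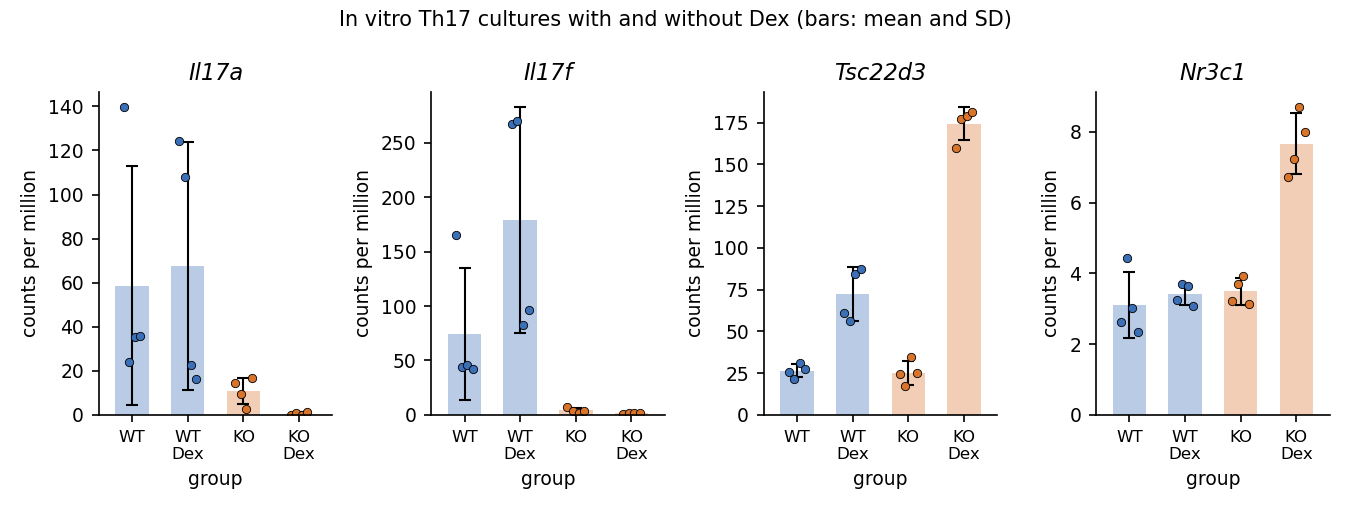
Levels of Il17a, Il17f, Tsc22d3 and Nr3c1 in CPM for each in vitro library (points), with the group mean and SD (bars), n = 4 per group. Il17a was 67.7 CPM in WT and 0.604 CPM in KO libraries with Dex, while Tsc22d3 was 72.4 and 174 CPM.

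The same comparison in IL-23R KO cells asked how cultures labelled IL-23R KO answered Dex. Tsc22d3 rose 9.55-fold (174 ± 9.75 against 25.2 ± 7.18 CPM, n = 4 each, edgeR adjusted p = 1.51e-09). Nr3c1 rose 3.02-fold (7.66 ± 0.863 against 3.50 ± 0.378 CPM, adjusted p = 4.05e-06). Ifng fell from 12.6 ± 5.94 to 0.162 ± 0.324 CPM (log2 fold change -5.50 ± 1.00, adjusted p = 1.94e-04). Fkbp5 did not pass the threshold (log2 fold change 0.27 ± 0.18, adjusted p = 0.240). Il23r fell (-1.02 ± 0.37, adjusted p = 0.0275), a call that was lost without KO Dex library 5 or 7 or KO control library 6 or 8 (adjusted p from 0.0556 to 0.0848). Il17a fell as well (-3.69 ± 1.42, adjusted p = 0.0361), but not without KO Dex library 5, 6 or 7 or KO control library 5, 6 or 8 (adjusted p from 0.0525 to 0.0857). Adm rose from 4.43 ± 1.24 to 93.9 ± 10.1 CPM (log2 fold change 4.86 ± 0.16, adjusted p = 2.55e-12), and Plaur, Il23a, Isg20 and Tgfb3 each rose by over 4 on the log2 scale. Il5 was counted 1 time over the 4 KO Dex libraries and 1116 times over the KO controls. Dclk1, listed at 0 with Dex, was at least 73.9-fold lower in CPM, and Pth at least 73.3-fold lower. These bounds were not scaled for the larger share of repeat counts with Dex, which raises them.

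In KO cells 5911 of 10813 genes (54.7%) differed between cultures with and without Dex, 2950 higher and 2961 lower with Dex. Of these, 1269 rose and 1138 fell by at least 1 on the log2 scale. The KO libraries with Dex also stood apart as libraries, with the most repeat counts and the smallest share of mitochondrial counts, 0.359 to 0.447% against 1.46 to 2.26% in the other 12 in vitro libraries. The groups did not overlap in CPM for 5707 genes (52.8%; chance 2.86%), a share that the unequal repeat counts can raise. Of the 23 lists tested, 9 were called by camera, and none held with an estimated correlation (adjusted p = 0.208 or more with an estimated correlation). All 18 glycolysis genes rose (mean log2 fold change 1.03), among them Gpi1 (1.71 ± 0.09) and Pfkfb3 (2.05 ± 0.12). Of 34 proliferation genes 31 fell (mean -1.26), among them Top2a (-1.64 ± 0.10) and Plk1 (-2.16 ± 0.15). Glucocorticoid-induced genes rose (15 of 20 higher, 1 lower; 17 and 1 adjusted over the list alone), and oxidative phosphorylation genes fell (29 of 38 lower, 1 higher; 30 and 2 adjusted over the list alone). Cholesterol synthesis, co-inhibitory receptor, Th1 and Tfh genes were lower and ribosomal protein genes higher. The last 3 of these were lost without 1 library. For Th1 this was KO Dex library 5 (camera adjusted p = 0.0543), and for ribosomal proteins KO control library 6 (0.0538). For Tfh it was KO Dex library 5 or 6 or KO control library 7 (0.0516 to 0.0547). Fry, which tests movement in 1 direction and does not compare a list with other genes, called 19 of the lists in KO cells.

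The interaction term tested whether the Dex effect itself differed between genotypes. It did for 3487 of 10813 genes (32.2%), 1623 with a more positive and 1864 with a more negative response in KO cells. The term includes the 4 KO libraries with Dex, which stood apart in repeat counts and mitochondrial share. The Tsc22d3 response was 3.21-fold larger in KO than in WT cells (interaction log2 fold change 1.68 ± 0.28, edgeR adjusted p = 2.36e-04), and the Nr3c1 response 2.56-fold larger (1.36 ± 0.30, adjusted p = 0.00222). Fkbp5 went the other way (-0.78 ± 0.25, adjusted p = 0.0239), a call lost without KO Dex library 7 (adjusted p = 0.0507). Il23r differed too (-1.67 ± 0.45, adjusted p = 0.00964), and Il17a (-3.98 ± 1.56, adjusted p = 0.0606) and Il17f (-2.14 ± 1.12, adjusted p = 0.158) did not pass. Adm (5.35 ± 0.27, adjusted p = 4.23e-09) had a much larger response in KO cells, and Spp1 (-5.98 ± 1.11) a much more negative one. All 18 glycolysis genes responded more positively in KO cells (mean 1.01), and 31 of 34 proliferation genes more negatively (mean -1.19), 1 being more positive. Of 20 glucocorticoid-induced genes 12 responded more positively and 1 more negatively (13 and 1 adjusted over the list alone). Oxidative phosphorylation (17 of 38 lower, 2 higher; 18 and 3 adjusted over the list alone) and cholesterol synthesis genes (11 of 22 lower, 2 higher; 11 and 3) responded more negatively. These 5 lists were called by camera, and none held with an estimated correlation (adjusted p = 0.251 or more with an estimated correlation). Of the 874 genes changed by Dex in WT cells, 304 had a larger response in KO cells, 121 a smaller or opposite one, and 449 were not called. Their median absolute log2 fold change was 0.61 in WT and 0.89 in KO cells. Of the 420 genes that rose with Dex in WT cells, 321 also rose in KO cells where 114.6 would be shared by independent draws, and 333 of the 454 that fell also fell (124.3 by independent draws).

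**Figure D2:**
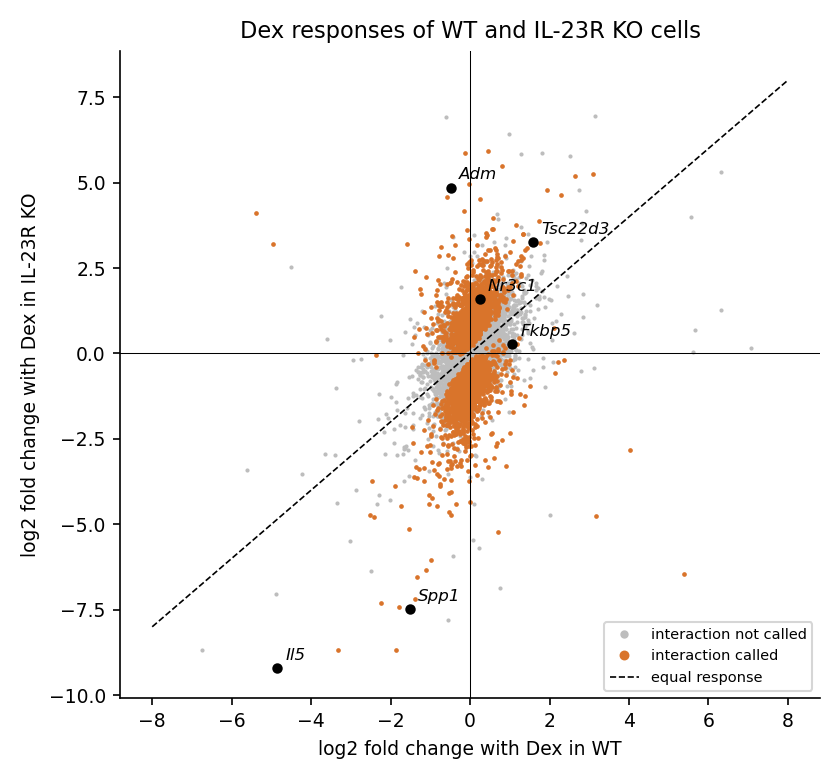
Log2 fold change with Dex in WT cells (horizontal axis) and in IL-23R KO cells (vertical axis) for 10813 tested genes, grey where the interaction was not called and coloured where it was. Across genes Pearson r was 0.471, and the dashed line marks equal responses.

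**Figure D3:**
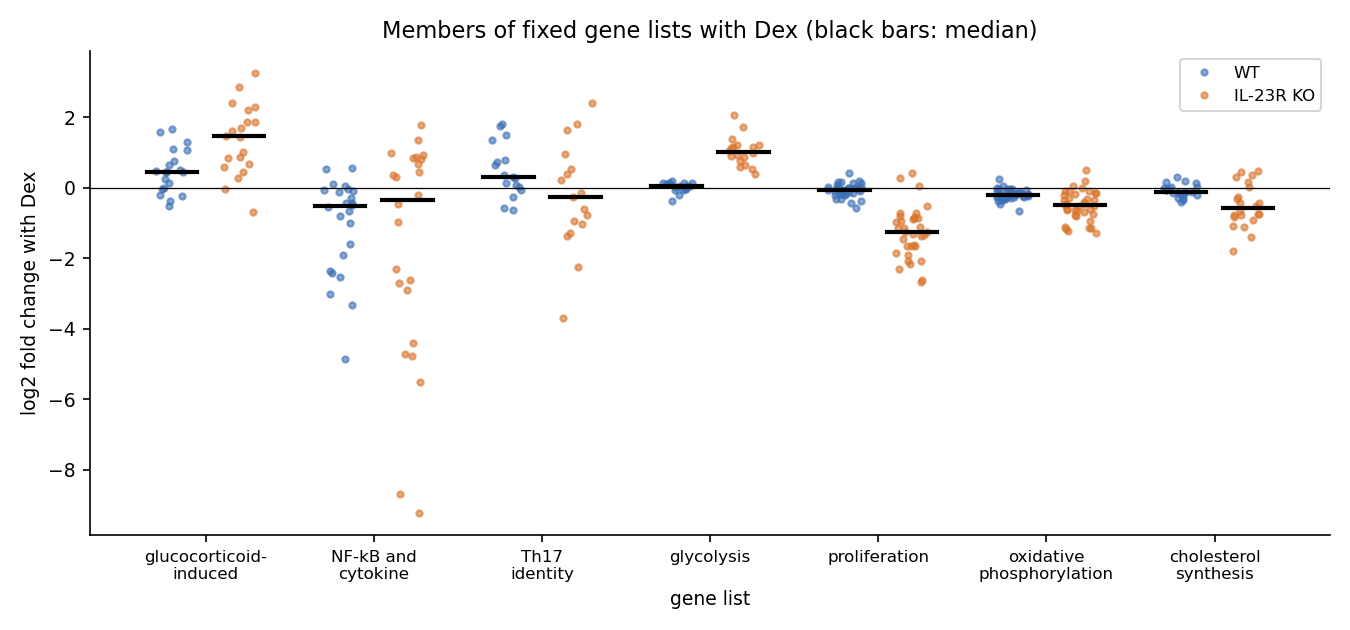
Log2 fold change with Dex of each tested member (points) of 7 fixed gene lists in WT and in IL-23R KO cells, with the list median (bars). All 18 glycolysis genes lie above 0 in KO cells, and 31 of 34 proliferation genes passed the threshold as lower.

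Without Dex, the comparison of KO with WT cultures asked how the labelled genotypes differed on their own. Il17f was 4.11 ± 2.33 CPM in KO and 74.3 ± 60.5 CPM in WT libraries (n = 4 each; log2 fold change -4.20 ± 0.61, edgeR adjusted p = 0.00204). The WT mean was raised by WT library 1, at 165 CPM against 42.5 to 45.8 CPM in the other 3, and the log2 fold change was -3.44 without it. Enpp2 was 3.87 ± 1.45 and 55.8 ± 15.4 CPM (-3.89 ± 0.36, adjusted p = 1.63e-05), and Timp1 76.1 ± 26.3 and 275 ± 26.5 CPM (-1.90 ± 0.27, adjusted p = 0.00153). Il17a (-2.45 ± 0.70, adjusted p = 0.157), Il23r (-0.74 ± 0.29, adjusted p = 0.397) and Ifng (1.75 ± 0.60, adjusted p = 0.309) did not pass. Cd24a (-2.36 ± 0.32) was lower and H2-Eb1 (1.31 ± 0.16) and Mid1 (2.50 ± 0.32) were higher in KO libraries. Tpm3-rs7 was 214 ± 25.7 in KO and 0.658 ± 0.679 CPM in WT libraries, and Tpm3 178 ± 12.9 and 384 ± 9.22 CPM. These 2 genes share sequence, and which of them the reads came from is uncertain.

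Only 74 of 10813 genes passed the threshold in that comparison, 24 higher and 50 lower in KO cells. The count fell to 26 without KO library 8, 34 without KO library 6, and 45 without WT library 1 or WT library 4. DESeq2 called 114 genes, 67 of them shared. The groups did not overlap for 588 genes (5.44%; chance 2.86%). The Th17 identity list was lower (3 of 17 members past the threshold; 9 lower adjusted over the list alone; mean log2 fold change -0.85), and it was the only list of the 23 that held with an estimated correlation (adjusted p = 0.0498 with an estimated correlation). Camera also called Th1 and interferon response genes higher and ribosomal protein genes lower. The number of lists called was 2 without WT library 1 or 4 and 7 without KO library 7, against 4 with all libraries. The Th1 call was lost without WT library 1 (camera adjusted p = 0.0811), the interferon call without WT library 1 or 4 (0.0723 and 0.0718), and the ribosomal call without KO library 6 or 8 or WT library 4 (0.0724 to 0.248). Genes lower in KO cells and raised by Dex in WT cells numbered 15 (1.94 by independent draws), and genes higher in KO cells and lowered by Dex numbered 8 (1.01). Higher in both were 1 (0.932 by independent draws) and lower in both 3 (2.10). These comparisons share the WT control libraries, which favours overlap in the same direction.

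With Dex, KO and WT cultures differed far more. The KO libraries with Dex are again those with the most repeat counts and the smallest mitochondrial share. Il17f was 1.75 ± 0.488 in KO and 179 ± 104 CPM in WT libraries (n = 4 each; log2 fold change -6.34 ± 0.68, edgeR adjusted p = 1.20e-06), Il17a 0.604 ± 0.740 and 67.7 ± 56.3 CPM (-6.43 ± 1.11, adjusted p = 1.70e-04), and Il23r 1.64 ± 0.407 and 10.9 ± 4.82 CPM (-2.41 ± 0.33, adjusted p = 1.87e-05). Tsc22d3 was 2.97-fold and Nr3c1 2.77-fold higher in KO cells (adjusted p = 2.78e-06 and 1.41e-05), and Fkbp5 did not pass (-0.30 ± 0.17, adjusted p = 0.168). Adm (4.79 ± 0.16) and Plod2 (2.70 ± 0.21) were higher, and Gzma (-4.42 ± 0.49) and Enpp2 (-3.99 ± 0.32) lower. The threshold was passed by 4967 of 10813 genes, 2400 higher and 2567 lower. The groups did not overlap in CPM for 4871 genes (45.0%; chance 2.86%), a share that the unequal repeat counts can raise. The Th17 identity list was lower (11 of 17 members lower, 3 higher, both counts unchanged adjusted over the list alone; mean -1.60). Proliferation (31 of 34), oxidative phosphorylation and cholesterol synthesis genes were lower, and glycolysis (18 of 18) and glucocorticoid-induced genes higher. None of these 6 lists held with an estimated correlation (adjusted p = 0.286 or more with an estimated correlation).

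In CNS cells, GR cKO was compared with WT to ask which genes depend on the receptor during disease. No gene passed the threshold by edgeR among 11148 tested, although 1226 had an unadjusted p under 0.05 and DESeq2 called 113. Without GR cKO library 5 the count was 2, and it was 1 without cKO library 6, WT library 1 or WT library 3. The groups did not overlap for 745 genes (6.68%; chance 2.86%). Nr3c1 had the smallest p value (5.52 ± 0.197 against 14.6 ± 2.84 CPM, n = 4 each; log2 fold change -1.30 ± 0.16, adjusted p = 0.113). The glucocorticoid-induced list was not called (mean log2 fold change -0.08, camera adjusted p = 0.137), with 8 of its 22 members positive and 14 negative, 0 past the threshold over all genes tested and 3 lower adjusted over the list alone. Among genes known to be induced by glucocorticoids, Tsc22d3 was 62.8 ± 11.2 in cKO and 144 ± 30.6 CPM in WT libraries (-1.09 ± 0.17, adjusted p = 0.153), Ddit4 9.47 ± 1.88 and 20.9 ± 2.37 CPM (-1.05 ± 0.15, adjusted p = 0.153), and Txnip 56.8 ± 6.43 and 105 ± 20.1 CPM (-0.78 ± 0.14, adjusted p = 0.157). All 4 cKO libraries lay under all 4 WT libraries for Tsc22d3. Fkbp5 was 11.9 ± 5.37 and 11.8 ± 0.993 CPM. Igkc, an antibody gene, was 228 ± 172 and 8.71 ± 4.66 CPM (4.82 ± 0.81, adjusted p = 0.153). Of 24 lists, 6 were called by camera and none held with an estimated correlation (adjusted p = 0.103 or more with an estimated correlation). The B cell and antigen presentation list was higher, with 0 of 11 members past the threshold over all genes tested and 11 adjusted over the list alone (mean log2 fold change 1.59). The cytokine receptor list, among it Il2rb (-0.53 ± 0.11) and Cish (-0.56 ± 0.14), was lower (mean -0.22; 0 of 26 members over all genes tested, 2 adjusted over the list alone), as were Treg (mean -0.28) and cholesterol synthesis genes (-0.34). Microglia and macrophage genes (0.46) and ribosomal protein genes (0.14; 45 of 45 positive) were higher. The cytokine receptor list alone was also called by fry. With a covariate of macrophage and antigen-presentation genes, 3 of the 6 calls held in their direction, and the Treg and cholesterol synthesis calls were lost. The covariate was made from the microglia and macrophage list and the B cell and antigen presentation list, so it tests neither of them. The mean of the microglia and macrophage list was -0.69 with this covariate, which contains it, and -0.039 without doubted libraries.

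**Figure D4:**
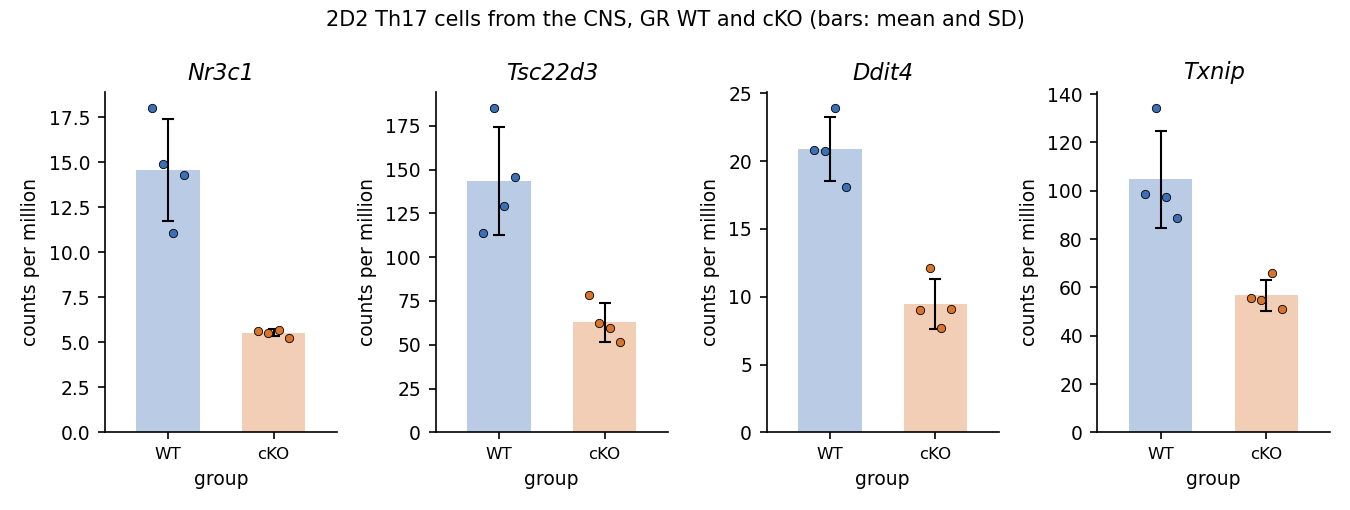
Levels of Nr3c1, Tsc22d3, Ddit4 and Txnip in CPM for each CNS library of the GR table (points), with the group mean and SD (bars), n = 4 per group. Nr3c1 was 14.6 CPM in WT and 5.52 CPM in cKO libraries, and no gene passed the adjusted threshold.

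Libraries labelled CHD1 cKO were compared with WT in the CNS to ask what the chromatin remodeller CHD1 affects there. One gene, Cd209a, passed the threshold among 11157 tested (32.9 ± 11.2 in cKO, n = 4, against 3.82 ± 0.563 CPM in WT, n = 3; log2 fold change 2.93 ± 0.30, edgeR adjusted p = 0.0259). It no longer passed without WT library 1, 2 or 3 or cKO library 3 (adjusted p from 0.0627 to 0.316), nor with a replicate block, without doubted libraries or with a covariate of macrophage and antigen-presentation genes (adjusted p = 0.356 with the covariate, the highest of all alternatives, which began at 5.10e-14). RNA of macrophages or antigen-presenting cells may add to the gene differences given here, and it was not told apart from a change in the T cells. The count was 2 without cKO library 1 or 4. DESeq2 called 176 genes, and 1326 had an unadjusted p under 0.05. The groups did not overlap for 1573 genes (14.1%; chance 5.71%). H2-Ab1 (1.31 ± 0.21) and Clec10a (1.43 ± 0.25) were higher and Ogt (-1.06 ± 0.16), Ahnak (-0.99 ± 0.15) and Hist1h3i (-2.17 ± 0.31) lower, each with adjusted p = 0.15. Il17f was 0.591 ± 0.657 in cKO and 8.28 ± 9.42 CPM in WT libraries (-3.86 ± 0.88, adjusted p = 0.236), and Ifng 122 ± 86.9 and 24.5 ± 0.987 CPM (2.15 ± 0.51, adjusted p = 0.236). Neither of these differences passed. Of 25 lists 10 were called by camera, 0 by fry and 0 with an estimated correlation (adjusted p = 0.302 or more with an estimated correlation). Interferon response genes were higher (mean 0.80; 0 of 30 members over all genes tested, 17 adjusted over the list alone), among them Usp18 (1.07 ± 0.23) and Bst2 (0.88 ± 0.19). Cholesterol synthesis genes were higher (mean 0.58; 0 of 22, and 11 adjusted over the list alone), among them Fdps (1.15 ± 0.20). B cell and antigen presentation genes (mean 1.14; 0 of 10, and 7 adjusted over the list alone), microglia and macrophage genes (0.42), oxidative phosphorylation genes (0.17) and proliferation genes (0.18) were also higher. The proliferation call was lost without cKO library 4 or WT library 1 (camera adjusted p = 0.685 and 0.312). Th17 identity (mean -0.69), Tfh (-0.66), chromatin remodeller (-0.25) and ribosomal protein genes (-0.24) were lower. The covariate contains the microglia and macrophage genes and the B cell and antigen presentation genes, so it tests neither list. With it the mean of the microglia and macrophage genes was -0.36 and the chromatin remodeller call was lost. Of the 10 list calls, 7 held without doubted libraries, and 9 each with a replicate block and in the joint fit of both tissues.

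In the dLN the same genotypes were compared to ask whether CHD1 acts outside the inflamed tissue. The chemokine gene Ccl1 was 3.13 ± 0.472 in cKO (n = 4) and 20.8 ± 7.44 CPM in WT libraries (n = 3; log2 fold change -2.60 ± 0.25, edgeR adjusted p = 0.0123). Slc43a3 was 6.30 ± 1.03 and 22.2 ± 1.99 CPM (-1.71 ± 0.20, adjusted p = 0.0300). Cd8a, a gene of CD8 T cells, was 59.2, 148, 92.0 and 20.4 CPM in cKO libraries 1 to 4 and 1.74, 0.318 and 1.07 CPM in WT libraries (6.17 ± 0.76, adjusted p = 0.0355), and Cd8b1 was 232 ± 145 and 16.4 ± 2.75 CPM (3.84 ± 0.51, adjusted p = 0.0355). Actn2 was 3.94-fold higher (adjusted p = 0.0355). In all, 7 of 9803 genes passed, 3 higher and 4 lower, the others being Gm11027 and Igkv4-91, named after their values were seen. DESeq2 called 319 genes, and 1971 had an unadjusted p under 0.05. The count was 0 without cKO library 2 or 3 or WT library 1 or 2, 2 without WT library 3, where Slc43a3, Cd8a, Cd8b1 and Actn2 no longer passed, and 990 without cKO library 4. The groups did not overlap for 1074 genes (11%; chance 5.71%). Cell cycle genes were lower without passing one by one, such as Aurka (5.87 ± 2.21 against 19.0 ± 4.83 CPM; -1.52 ± 0.31, adjusted p = 0.0719) and Cdc20 (-1.51 ± 0.33, adjusted p = 0.0762). Tsc22d3 was 202 ± 73.8 and 88.4 ± 17.0 CPM (1.22 ± 0.23, adjusted p = 0.0655), and Foxp3 was at least 13.7-fold higher against 0 counts in WT libraries (adjusted p = 0.0641). Of 24 lists 10 were called by camera and none held with an estimated correlation (adjusted p = 0.273 or more with an estimated correlation). The proliferation list was lower (mean -1.23; 0 of 33 members over all genes tested, 32 adjusted over the list alone). Stem-like and central memory genes were higher (mean 0.83; 0 of 17, and 11 adjusted over the list alone), as were interferon response (0.67) and non-pathogenic Th17 genes (0.72). CD8 T and NK cell genes were higher (mean 3.29; 2 of 5, and 4 adjusted over the list alone), the only list here that fry also called. RNA of CD8 T cells in the cKO libraries may therefore add to the gene and list differences given here. No covariate for such RNA was run in this comparison. Th17 identity (-0.65), glycolysis (-0.28) and oxidative phosphorylation genes (-0.22) were lower, and ribosomal protein (0.15) and B cell and antigen presentation genes (0.52) higher. The B cell call was lost without cKO library 2 or 3 or WT library 2 (camera adjusted p from 0.0736 to 0.859).

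**Figure D5:**
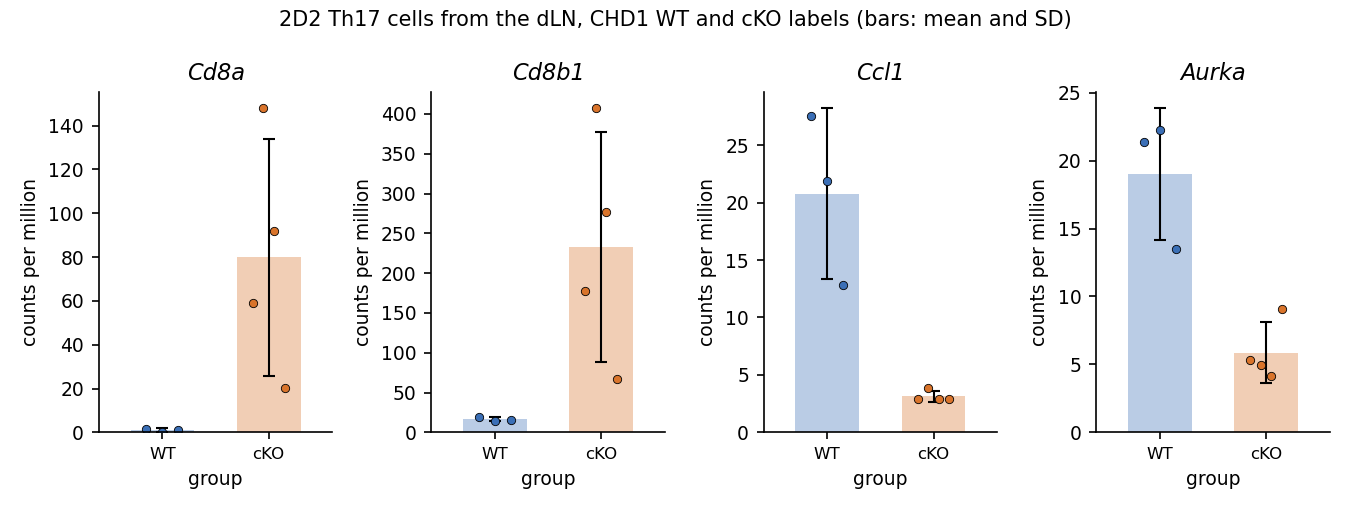
Levels of Cd8a, Cd8b1, Ccl1 and Aurka in CPM for each dLN library of the CHD1 table (points), with the group mean and SD (bars), n = 3 WT and n = 4 cKO. The cKO libraries lie above all WT libraries for Cd8a, at 20.4 to 148 CPM.

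The interaction of genotype with tissue tested whether the CHD1 effect differed between CNS and dLN. It passed for 13 of 11589 genes, 5 with a more positive and 8 with a more negative effect in the CNS. DESeq2 called 575, and 2190 had an unadjusted p under 0.05. Ccl1 (interaction log2 fold change 3.32 ± 0.49, edgeR adjusted p = 0.0304) and Slc43a3 (1.93 ± 0.30, adjusted p = 0.0365) had the more positive effect in the CNS, and Cd8b1 (-3.97 ± 0.57, adjusted p = 0.0297), Ogt (-1.46 ± 0.21, adjusted p = 0.0297) and Lef1 (-1.74 ± 0.30, adjusted p = 0.0472) the more negative. Il17f (-5.69 ± 1.46, adjusted p = 0.0929) did not pass. The term includes the cKO dLN libraries, where RNA of CD8 T cells may add to the gene and list differences given here. The count was 0 without any 1 of the 3 WT CNS libraries, without cKO dLN library 1, 2 or 3, or without WT dLN library 1 or 2. It was 6 without cKO CNS library 1, 28 without cKO CNS library 2, 8 without cKO CNS library 3, 24 without WT dLN library 3 and 648 without cKO dLN library 4. The Lef1 call was also lost without cKO CNS library 1, 3 or 4 (adjusted p from 0.0544 to 0.0714). Proliferation genes responded more positively in the CNS (mean 1.37; 0 of 34 members over all genes tested, 31 adjusted over the list alone). Oxidative phosphorylation (0.38), cholesterol synthesis (0.48), glycolysis (0.30) and microglia and macrophage genes (0.77) did so too. Ribosomal protein (-0.40), stem-like (-0.86), chromatin remodeller (-0.36), non-pathogenic Th17 (-1.05) and CD8 T and NK cell genes (-2.14) responded more negatively. None of these 10 lists, of 27 tested, held with an estimated correlation (adjusted p = 0.419 or more with an estimated correlation). The glycolysis call was lost without WT CNS library 1 (camera adjusted p = 0.0502), the non-pathogenic Th17 call without cKO CNS library 4, WT CNS library 2, cKO dLN library 1 or WT dLN library 1 (0.0507 to 0.0584), and the macrophage call without cKO CNS library 2, WT CNS library 1 or 3, cKO dLN library 3 or WT dLN library 3 (0.050 to 0.121). Without WT dLN library 3 the mean of the macrophage list was -0.14.

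CNS and dLN libraries of CHD1 WT donors were compared to describe how the sorted cells differed between the tissues. The CNS and dLN libraries came in separate tables, so tissue and table cannot be told apart, and repeat and ribosomal RNA features took 24.7 ± 7.49% of WT CNS and 48.3 ± 6.28% of WT dLN counts. Ifng was 24.5 ± 0.987 in the CNS and 0.932 ± 0.866 CPM in the dLN (n = 3 each; log2 fold change 4.43 ± 0.76, edgeR adjusted p = 9.33e-04). Il17f was 8.28 ± 9.42 and 0.237 ± 0.249 CPM (4.48 ± 1.09, adjusted p = 0.0108; 0.0911 without CNS library 2). Nr3c1 was 2.26-fold higher in the CNS (adjusted p = 0.0103; 0.0524 without CNS library 1). S1pr1 was 10.7 ± 0.0708 in the CNS and 60.5 ± 5.11 CPM in the dLN (-2.88 ± 0.32, adjusted p = 2.06e-05). Dusp1 was 27.6-fold higher in the CNS (228 ± 27.4 against 6.12 ± 1.73 CPM, adjusted p = 5.12e-08). Genes of microglia were counted in the sorted CNS libraries, so RNA of other cells may add to the gene and list differences given here. No covariate for such RNA was run in this comparison. C1qa was 541 ± 124 against 0.320 ± 0.321 CPM (10.15 ± 0.59, adjusted p = 5.83e-08). Tmem119 was 67.5 ± 15.6 CPM in the CNS and listed at 0 in the dLN, at least 267-fold higher in CPM. That bound was not scaled for the larger share of repeat counts in the dLN, which raises it. In all 1938 of 11589 genes passed, 1367 higher and 571 lower in the CNS. The groups did not overlap in CPM for 4831 genes (41.7%; chance 10%), a share that the unequal repeat counts can raise. Camera called 18 of 27 lists, and 9 held with an estimated correlation. These 9 were all higher in the CNS and were microglia and macrophage genes (23 of 23 members), immediate early and stress genes (21 of 24), NF-kB and cytokine genes (18 of 26; 23 adjusted over the list alone), co-inhibitory receptors (12 of 16 higher, 1 lower; 13 and 1 adjusted over the list alone), Treg (7 of 14; 11 adjusted over the list alone), Th17 identity (9 of 16; 11), pathogenic Th17 (6 of 13 higher, 1 lower; 8 and 1), Th1 (7 of 16; 9) and cytokine receptor genes (11 of 26 higher, 2 lower; 14 and 2). Glycolysis, interferon response, cholesterol synthesis, glucocorticoid-induced, apoptosis regulator, neural and glial, and non-pathogenic Th17 genes were also called higher, and stem-like and chromatin remodeller genes lower. The non-pathogenic Th17 call was lost without CNS library 2 or dLN library 2 (camera adjusted p = 0.0582 and 0.0695), and the chromatin remodeller call without CNS library 2 or dLN library 3 (0.0533 and 0.0753). The lists of neutrophil, erythroid and endothelial, and homing and adhesion genes were called in no comparison. Mean, median and camera direction had the same sign for every list called in any comparison.

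Fold changes were set side by side across genes, which are not independent replicates, with a family of 4 exact permutation tests over splits of the labels, two-sided, and Benjamini-Hochberg adjustment. None of the 4 passed after adjustment. The Dex responses of WT and KO cells gave Pearson r = 0.471 and Spearman 0.451 across 10813 genes, with an exact permutation p = 0.0286, the smallest that 35 splits can give, and an adjusted p of 0.114. Another split of the labels reached an absolute r of 0.413, and r ran from 0.417 to 0.481 without 1 library. The GR cKO effect in the CNS and the Dex effect in WT cells were not detectably related (Pearson r = -0.034, Spearman 0.014 across 9973 genes; exact permutation p = 0.80, adjusted 0.943). The GR cKO and CHD1 cKO effects in the CNS gave Pearson r = 0.158 and Spearman 0.131 across 10794 genes (exact permutation p = 0.257, adjusted 0.514), with a jackknife SE of 0.135 over libraries and a range of 0.097 to 0.222 without 1 library. The CHD1 effects in CNS and dLN gave Pearson r = 0.0082 and Spearman -0.107 across 9591 genes (exact permutation p = 0.943, adjusted 0.943). The IL-23R KO effect without Dex and the Dex effect in WT cells share the WT control libraries, which alone pushes r upward. Their r was 0.134 (jackknife SE 0.143 over libraries), and 100 simulations without any effect gave 0.492 ± 0.017. The simulations held no Dex effect, which in the data widens the fold changes and lowers r, so these r values cannot be compared directly. The covariance, which is not divided by that spread, was 0.0188 in the data and 0.0341 ± 0.0017 in the simulations. The simulated SD leaves out the spread over real libraries, so no conclusion was drawn. With the WT controls split so that no library was shared, the mean r was -0.091, and it ranged from -0.134 to -0.028 over 6 assignments.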

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

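The tests of low oxygen, of equal depth after removal of repeat counts, and of T cells with another receptor were chosen after the results were seen.

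Each of several measures was checked in each group of 4 libraries, 127 checks in all. In 3 of them a library lay far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. These flags are therefore no more than chance gives, and the measures are not independent. The mitochondrial share was 1.89% in GR cKO library 9 and 2.05 to 2.06% in the other 3. Il17a was 139.6 CPM in in vitro WT control library 1 and 24.1 to 35.7 CPM in the others, and Il17f was 165 CPM there and 42.5 to 45.8 CPM in the others.

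The Dex effect differed between IL-23R KO and WT cells, by the interaction test, for 3487 genes. Among the genes named in the report the interaction log2 fold change was 5.35 for Adm, 1.68 for Tsc22d3 and 1.36 for Nr3c1. It was -5.98 for Spp1, -1.67 for Il23r and -0.78 for Fkbp5. The mean over a list was 0.87 for glucocorticoid-induced and 1.01 for glycolysis genes. It was -1.19 for proliferation, -0.31 for oxidative phosphorylation and -0.41 for cholesterol synthesis genes. None of these lists held with an estimated correlation.

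The larger Dex response of KO cells was weighed against technical explanations. Sequencing depth and repeat counts as the whole cause were argued against by 2992 interaction genes with repeat counts removed and every library thinned to equal depth, and GC content with transcript length by a smooth fit that explained 1.37% of the variance of the interaction values. RNA degradation was argued against by a Spearman rho between transcript length and interaction value of 0.107 ± 0.0099 (bootstrap SE), since loss of long transcripts needs a negative one. A candidate explanation is low oxygen in the KO cultures with Dex. A list of 23 HIF targets outside the fixed lists had a mean interaction log2 fold change of 1.28 (bootstrap SE over members 0.144). In it 18 members were higher and 0 lower past the threshold. Its means were 0.10 with Dex in WT cells and -0.00084 between KO and WT cells without Dex. The camera p with an estimated correlation was 0.0169, not adjusted. The fixed lists were judged on adjusted p values, so this p does not set the HIF list apart from them. Plod2, a member, is also named above as higher in KO cells with Dex. HIF activity raised by another route, any condition shared by the 4 KO cultures or libraries with Dex, which also held the most repeat counts and the smallest mitochondrial share (0.412 ± 0.0375%), and an effect of the IL-23R genotype on the Dex response all stay open as untested.

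The in vitro group comparisons called more genes with the labels than in any other split of the same libraries, which argues against a chance division of them. A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over comparisons. The splits tell nothing of a condition shared by the libraries of a group. With the labels the count was 874 for Dex in WT cells and at most 1 in any other split, and only 1 of 35 splits, the real one, gave as many. The same held for Dex in KO cells (5911, highest other split 1), for KO against WT without Dex (74, highest other split 10) and for KO against WT with Dex (4967, highest other split 3), each with 1 of 35 splits as large. For the interaction 1 of 50 splits, the real one, reached 3487, but another split called 2913 genes. Genotype labels were moved within the Dex and within the control libraries, so a split can keep the KO against WT difference with Dex. The 50 splits therefore do not test the interaction apart from that difference.

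Differences between tissues in the CHD1 cKO effect were called for 13 genes by the interaction test. The log2 fold change was 3.32 for Ccl1, 1.93 for Slc43a3, -3.97 for Cd8b1, -1.46 for Ogt and -1.74 for Lef1. List means were 1.37 for proliferation, 0.30 for glycolysis, 0.38 for oxidative phosphorylation, 0.48 for cholesterol synthesis and 0.77 for microglia and macrophage genes. They were -1.05 for non-pathogenic Th17, -0.86 for stem-like, -0.36 for chromatin remodeller, -0.40 for ribosomal protein and -2.14 for CD8 T and NK cell genes. None of these lists held with an estimated correlation, and the macrophage mean was -0.14 without WT dLN library 3. RNA of CD8 T cells in the cKO dLN libraries may add to these gene and list values. Of 50 splits 2 gave as many genes, a share narrowly under the 0.05 set for excluding chance, and the other of these called 243 genes, which points to a structure of the samples. The count also fell to 0 without any of 8 single libraries.

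For the genotype comparisons of the CHD1 tables chance could not be excluded. In the CNS 5 of 35 splits gave as many as the real 1 gene, the highest other split also giving 1. In the dLN 2 of 35 splits gave as many as the real 7 genes, and a split that put cKO library 4 with the 3 WT libraries called 1042, which points to a structure of the samples. For GR the splits decide nothing, because a real count of 0 by edgeR (1226 genes at an unadjusted p under 0.05, and 113 by DESeq2) is reached by all 35, with 37 in the highest other split. For CNS against dLN in WT donors the 10 splits are too few for a share under 0.05, with 1938 genes in the real split, the 1 as large, and 0 in the highest other.

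In the dLN, the proliferation list had a median log2 fold change of -1.38 in cKO libraries (jackknife SE 0.578 over libraries), with 0 of 33 members past the threshold over all genes tested and no call with an estimated correlation (adjusted p = 0.50; 1.20e-26 to 0.50 over its alternatives). The median lay lower than the log2 ratio of the mean Trbv16 shares (96.4% in cKO and 99.4% in WT libraries) by over 2 SE. The difference was -1.33 with a jackknife SE of 0.572 (-1.25 with an SE of 0.563 by the mean Trav9-3 shares, 82.1% and 89.7%). This cannot decide on T cells with another receptor, because a share of Trbv counts need not be a share of cells. Mean Trbv counts per library were 38938 in the WT dLN and 3611 in the in vitro WT controls, whose receptors were mixed. Dilution of 2D2 cells by any other cells cannot be told apart from a change within them. Trbv16 itself had a log2 fold change of -0.90 ± 0.28 (edgeR adjusted p = 0.136), and the median differed from it by -0.48 with a jackknife SE of 0.575, too wide to decide. An effect of the CHD1 genotype on division and a different mixture of sorted cells both stay open.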

How the results depend on the processing

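The fits with repeat counts removed, with equal depth, with the covariate and without doubted libraries were chosen after the results were seen. The pseudocount alternative was not run because it does not apply to counts. No paired analysis was possible for GR because WT numbers 1 to 4 and cKO numbers 5, 6, 7 and 9 share none.

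For the gene counts, 113 alternative values were within 1.5 times the reported count and 58 were not. Dex in KO cells gave 4227 to 5955 genes over all alternatives run, KO against WT with Dex 3682 to 4980 and the genotype by Dex interaction 2818 to 3643. The count for Dex in WT cells, 874, ranged from 531 to 829 when 1 library was left out, and CNS against dLN gave 1225 of 1938 with a mean of at least 10 CPM, where fewer genes were tested. KO against WT without Dex gave 114 by DESeq2 (67 shared), 42 in a fit of only the 8 libraries compared (39 shared) and 26 to 77 without 1 library, against 74.

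The CHD1 and GR counts depended on the tool and on single libraries, and the cause was not tested. Against 1 gene, CHD1 in the CNS gave 176 by DESeq2, 72 with no filter, 3 in the joint fit of both tissues, 0 without doubted libraries and 0 to 2 without 1 library. With the covariate it gave 1 other gene (0 shared), as Cd209a did not pass there (log2 fold change 2.80, adjusted p = 0.356; 5.10e-14 to 0.356 over its alternatives). Against 7, CHD1 in the dLN gave 319 by DESeq2, 511 with no filter, 192 in the joint fit, 58 with repeat counts removed and equal depth, 1 without doubted libraries and 0 to 990 without 1 library. GR gave 113 by DESeq2, 4 with no filter, 4 without doubted libraries and 0 to 2 without 1 library, against 0. The genotype by tissue interaction, with 13 genes, gave 575 by DESeq2, 7 with RLE factors, 172 with no filter, 95 with a mean of at least 10 CPM, 1 without doubted libraries and 0 to 648 without 1 library. The libraries doubted were WT CNS 3 and cKO CNS 1 and 3 of the CHD1 CNS table, cKO dLN 2 and 3, and GR WT 1 and cKO 5. In the GR table WT 1 held the least and cKO 5 the most Lyz2, a macrophage gene (198 and 1714 CPM). In the dLN cKO 2 and 3 held the most Cd8a (148 and 92.0 CPM). These fits are therefore not independent of the cell mixture.

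A replicate block, which treats equal numbers as paired, gave 3 genes for CHD1 in the CNS (0 shared), 613 in the dLN and 52 for the genotype by tissue interaction. Same-number libraries correlated at -0.080 to 0.109 after group means were removed, and no set had every pair above 0.1, so the numbers were not taken as pairs. Even so, 3 of 4 same-number pairs of WT control with WT Dex were each other's best match. This held for 2 of 4 pairs of CHD1 cKO CNS with dLN and for 1 pair in each other set. Pairing by number is therefore not excluded.

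Gene list counts were within 1.5 times for 154 alternative values and not for 25. With an estimated correlation camera called 0 lists for CHD1 in the CNS (10 with the preset), CHD1 in the dLN (10), GR (6), Dex in KO cells (9), KO against WT with Dex (6) and both interactions (5 for Dex and 10 for tissue). It called 1 for Dex in WT cells (12), 1 for KO against WT without Dex (4) and 9 for CNS against dLN (18). Fry called 0 lists for CHD1 in the CNS, 1 in the dLN, 1 for GR, 1 for KO against WT without Dex, 3 for the tissue interaction, 13 for the Dex interaction, 17 for KO against WT with Dex and 19 for Dex in KO cells. Fry and camera test different questions. With the covariate GR gave 8 lists, 3 of them shared with the 6 and the glucocorticoid-induced list (lower) among the others, and CHD1 in the CNS 10, of which 8 were shared. The covariate was made from the macrophage and B cell lists, so it tests neither of them. Dex in WT cells gave 7 lists in a fit of only the 8 libraries compared. KO against WT without Dex gave 8 with no filter, 7 with a mean of at least 10 CPM and 2 to 7 without 1 library, and the Dex interaction 8 with no filter. With a mean of at least 10 CPM some calls were lost. Those kept were 4 of 6 for KO against WT with Dex and 4 of 5 for the Dex interaction. For Dex in KO cells 7 of 9 were kept, and for Dex in WT cells 8 of 12.

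Of 90 lists called, 1372 alternative values were the same, 193 were weaker and 5 reversed. In 2 this was the microglia and macrophage list under the covariate that contains it, at -0.36 for CHD1 in the CNS and -0.69 for GR, so the reversal follows from its construction. That list also reversed without doubted libraries for GR (-0.039, against 0.46) and without 1 library for the tissue interaction, where it ran from -0.14 to 1.03 (0.77 with all). The Tfh list with Dex in WT cells (-0.20) was 0.11 with no filter. The cause of these 3 was not tested, although for GR the doubted libraries were the extremes of Lyz2, a member of that list. Of 71 named genes called, none reversed, with 1068 values the same and 104 weaker, and 54 genes were the same throughout. Of 35 named genes not called, 490 values were the same, 79 became calls and 8 reversed, and only 6 genes were the same throughout. Chd1 in the CNS (-0.05) ran from -0.16 to 0.10 without 1 library and was 0.022 without doubted libraries. Il17a with Dex in WT cells (0.29) ran from -0.18 to 1.19. Fkbp5 in GR cKO libraries (0.09) ran from -0.20 to 0.27, and was -0.14 with the covariate and -0.26 without doubted libraries. These 3 lay near 0, and the cause was not tested.

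Correlations kept their sign in 72 values and reversed in 12. GR with Dex in WT cells (-0.034) gave 0.014 by Spearman and -0.083 to 0.0059 without 1 library. CHD1 in the CNS with the dLN (0.0082) gave -0.107 by Spearman, -0.110 with a mean of at least 10 CPM in both and -0.041 to 0.068 without 1 library. KO against WT without Dex with Dex in WT cells (0.134) gave -0.091 with the WT control libraries divided so that no library was shared.

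Power was tested only in simulated data of the same depths and group sizes, so the part of depth was not separated. There, of 100 genes changed 2-fold, 41 were called in the CHD1 CNS design, 54 in the dLN, 62 in GR, 73 for Dex in WT cells and 15 for the tissue interaction, and of 100 changed 4-fold, 91, 92, 89, 94 and 62. Equal depth with repeat counts removed did not lower the dLN count (58 against 7) or that of the tissue interaction (19 against 13), while Dex in WT cells gave 713 against 874. False calls were 3.31 to 10.2% of the calls.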

Other observations

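The test of the Tpm3 pair was chosen after the result was seen, and the covariate was added then too.

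Without Dex, Tpm3 was called lower and Tpm3-rs7 higher in IL-23R KO than in WT cultures. Reads of Tpm3 counted under Tpm3-rs7 are a candidate explanation, because the scaled sum of both differed by -4.01 CPM (SE 7.59; exact permutation p = 0.514 over 35 splits) between KO (350.0 ± 10.9 CPM) and WT libraries (354.0 ± 10.5 CPM). A change in the use of these genes stays open as untested.

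With the macrophage and antigen-presentation covariate the mean of the interferon response list in the CHD1 CNS comparison was 0.86 (0.80 without it), with a range of 0.72 to 2.05 without 1 library and a jackknife SE of 1.07 over libraries, too wide to decide, so RNA from macrophages, microglia or antigen-presenting cells cannot be told apart from a change in the T cells for this list. The cytokine receptor list in the GR comparison was -0.29 ± 0.062 with the covariate (-0.22 without it; -0.32 to -0.24 without 1 library). The covariate does not measure the share of T cell RNA. Cd4 was 227 to 325 CPM in GR WT and 156 to 214 CPM in GR cKO libraries. Trbv16 was 9090 to 13938 and 6561 to 9946 CPM, with overlap. A smaller share of T cell RNA therefore cannot be told apart from a change in the T cells for this list either. Neither list held with an estimated correlation.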
